A study of Mus musculus with 9 samples.

How the data were processed

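Bone marrow stromal cells negative for CD45.1 and Ter119 were sorted from FVB/NJ mice, and total RNA was labelled for Affymetrix mouse expression arrays (3' labelling), per the labels. The labels put 3 arrays in wild type (WT), 3 in the early phase (E, 1 to 5% leukemic cells in the marrow) and 3 in the medium phase (M, 5 to 50%), and call them biological replicates. Latent and late phases named in the design are not analysed here. The deposited values are log2 MAS5 signals per the submitters' processing notes, with the version of MAS5 not given. Exact zeros in the deposited values correspond to linear signals of 1 or less. The mean linear signal of each array without the lowest and highest 2% of probe sets was the same in all arrays to within rounding, which is how MAS5 scales arrays. Signal over background differed between the groups: exact zeros numbered 499.7 ± 17.0 of 45101 probe sets in WT, 664 ± 100.1 in E and 300.0 ± 45.9 in M (SD, n = 3), and the median over all probe sets was 5.64 ± 0.04, 5.50 ± 0.09 and 6.26 ± 0.02 (log2). Within a group the arrays differed by a root mean square of 0.234 to 0.366 on average, which holds the spread between animals as well as that between arrays, and pairs of M arrays by 0.215 to 0.442.

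Values were used as deposited. The pseudocount of 16 planned for linear values was not used in the main fit, since the values were already logarithms, and pseudocounts of 1 and 64 on the linear scale were tried as alternatives. Of 45101 probe sets, 34958 carried a single gene symbol in the array's annotation, 932 carried several and 9211 were not listed, and the last 2 kinds were left out. A gene was represented by its probe set with the highest mean over the 9 arrays, which gave 18194 genes. The 9097 genes at or above the median of these means (log2 6.83) were tested. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model over all 9 arrays, moderated t with an intensity trend), with p adjusted by the Benjamini-Hochberg method and called under 0.05. SE values are those of the model. The comparisons were E with WT, M with WT and M with E, with an F test over the 3 groups and a test of whether the second step equals the first, all as moderated statistics of limma. M with WT is also the linear trend over 3 equally spaced groups. Spike-in controls were compared between groups by exact permutation of the arrays.

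Gene lists were fixed before the data were examined, from general knowledge: 32 lists of stromal cell types, blood cell types and pathways. Lists with at least 5 tested members, 24 in number, were tested with camera (correlation 0.01, Benjamini-Hochberg over the 24 lists), and again with an estimated correlation and with fry. They were mesenchymal niche, fibroblast matrix, osteoblast, chondrocyte, adipogenic, pericyte and smooth muscle, endothelial, pan-hematopoietic, granulocyte, erythroid, megakaryocyte, B lineage, stem and progenitor, cell cycle, ribosomal protein, oxidative phosphorylation, unfolded protein response, hypoxia and glycolysis, immediate early, inflammatory, interferon, TGF-beta, Notch and p53 lists. The Schwann cell, skeletal muscle, osteoclast, monocyte, T and NK cell, plasma cell and Wnt lists had too few members over the brightness filter and were followed without it. A list of 4 sex-linked genes was meant as a check for exchanged samples, and 0 of its genes were called in any comparison. Its 1 gene over the brightness filter, Xist, read between 13.7 and 14.2 (log2) in every array. Arrays so alike cannot show an exchange, so the check does not bear on it.

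Genes were named by a rule set in advance: the 10 largest rises and 10 largest falls of a comparison among genes with an adjusted p under 0.05 and arrays that did not overlap, the 4 members with the smallest p of up to 8 lists with the smallest camera p, and a fixed set of 22 genes of the niche and of contaminating cells. Some genes of the fixed set are not analysed here. Other genes are named with a statement that they were chosen after their values were seen.

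The pipeline was tested on simulated data with the spread of these arrays (100 simulations of 9097 genes with 200 changed). A log2 change of 1 was recovered in 86.5% of genes and a change of 2 in 98.7% in the E with WT setting, with 9.96 false calls on average, and in 87.0% and 98.8% with 9.61 false calls in the M with WT setting. A list of 14 genes shifted by 1 was called in 100 of 100 simulations, with 0.13 of 23 other lists called on average. Genes were drawn independently there, while the correlation within the real lists was estimated at up to 0.73. The simulations therefore do not show how often camera calls lists falsely in the real data.

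Alternatives tried were the pseudocounts, no brightness filter, a stricter filter that kept the 4549 brightest genes, quantile normalization, centring on the median, scaling on the poly-A spike-ins, limma without the trend, with robust estimation and with array weights, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridization, fitting only the 2 groups compared, the replicate number as a block, an adjusted p under 0.1, a 2-fold minimum, and leaving out each array. Replicate numbers shared between groups were checked as possible pairs: residuals of the 9 same-number pairs of arrays correlated at -0.10 to 0.08, and arrays were treated as unpaired. Between M and WT, of 1975 genes with several called probe sets, 48 had probe sets called in opposite directions, and 0 of these are named in the text. This was not counted for the other comparisons. Between E and WT, 88 of the 192 calls were kept with the mean of a gene's probe sets.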

Results

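Gene expression was measured on 9 Affymetrix mouse expression arrays with RNA from bone marrow stromal cells of FVB/NJ mice. The cells had been sorted as negative for CD45.1, a leukocyte surface marker, and for Ter119, an erythroid surface marker. Wild-type mice (WT) gave 3 arrays, leukemic recipients in the early phase (E, 1 to 5% leukemic cells in the marrow) gave 3, and recipients in the medium phase (M, 5 to 50%) gave 3. The arrays of a group are labelled biological replicates, so the p-values of single genes below measure the spread between those. Camera p-values of gene lists set the members against the other genes tested, and are by themselves no measure of that spread. Values are log2 MAS5 signals, and the number of arrays limits their precision. Of 18194 genes represented on the array, the 9097 with the brighter mean signal were tested. The question of the series was how gene expression of the stromal cells shifts step by step as leukemia progresses.

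The M arrays stood apart from all others. A principal component that carried 89.96% of the variance placed the M arrays between 68.4 and 90.3 and the WT and E arrays between -43.1 and -33.5. The root mean square log2 difference between arrays averaged 0.245 within WT and 0.234 within E, 0.331 between WT and E, 1.19 between WT and M, and 0.366 within M. Erythroid and cell cycle genes gave high signals in every group. The mean log2 signal of the named erythroid genes was 11.59 ± 0.09 in WT, 11.34 ± 0.06 in E and 11.57 ± 0.58 in M (SD, n = 3), and that of the cell cycle genes 12.46 ± 0.04, 12.36 ± 0.05 and 11.89 ± 0.28. Mesenchymal niche genes read far lower in WT and E, at 6.81 and 6.64, and 10.82 in M. Pericyte genes read 5.25, 5.03 and 7.85. The comparisons below are therefore of the sorted cells as a whole, and the share of RNA from stromal cells was not measured. Control RNAs added before labelling (poly-A spike-ins, 12 probe sets) read 2.01-fold higher in M than in WT, a log2 shift of 1.01 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays allow). They differed by -0.01 between E and WT (exact permutation p = 1). The 3' minus 5' log2 signal of Actb, a measure of RNA integrity, was 1.06 ± 0.08 in WT, 1.06 ± 0.10 in E and 1.17 ± 0.17 in M (SD, n = 3), and that of Gapdh was 0.07 ± 0.12, 0.07 ± 0.02 and 0.28 ± 0.18.

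The comparison of E with WT asks what differs in the sorted cells when leukemic cells are still few. In E, 10 of 13 measured cartilage genes, 8 of 18 immediate early genes and 6 of 12 inflammatory mediators fell, and of 10 granulocyte genes 5 rose and 2 fell. With an estimated correlation only the inflammatory list kept its call (adjusted p = 0.00735), while those of the cartilage, immediate early and granulocyte lists were lost (adjusted p = 0.114, 0.114 and 0.227). Col2a1, the main collagen of cartilage, fell by 0.77 (log2) from 12.87 ± 0.14 in WT to 12.10 ± 0.05 in E (SD, n = 3, adjusted p = 0.000230). S100a9, a calcium-binding protein of neutrophils, rose 5.66-fold from 8.16 ± 0.16 to 10.66 ± 0.08 (SD, n = 3, adjusted p = 2.54e-06). Niche factors that hold and feed blood stem cells did not pass the test at this phase. Cxcl12, the chemokine that retains stem cells in the marrow, was at 8.63 ± 0.11 in WT and 8.85 ± 0.07 in E (SD, n = 3, adjusted p = 0.252).

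Among 13 measured chondrocyte genes, 10 fell, 0 rose and 3 did not pass (11 fell with p adjusted over the list alone), with a median log2 change of -0.77. Besides Col2a1, the cartilage matrix genes Comp (-1.18 ± 0.09 SE, adjusted p = 7.09e-05), Col9a1 (-0.73 ± 0.07 SE, adjusted p = 0.000168) and Col10a1 (-1.67 ± 0.24 SE, adjusted p = 0.00392) fell. As a list, chondrocyte genes lay below the other genes (camera adjusted p = 2.28e-16, adjusted p = 0.114 with an estimated correlation). Of 18 immediate early genes, which respond within minutes to stimulation and to tissue dissociation, 8 fell and 10 did not pass (13 fell adjusted over the list alone), with a median of -0.67 (camera adjusted p = 3.34e-16, adjusted p = 0.114 with an estimated correlation). The transcription factor genes Jun (-1.08 ± 0.07 SE, adjusted p = 1.89e-05) and Fos (-0.94 ± 0.07 SE, adjusted p = 3.81e-05) and the phosphatase gene Dusp1 (-1.14 ± 0.10 SE, adjusted p = 0.000154) were among them. Of 12 inflammatory mediators, 6 fell and 6 did not pass (8 fell adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.52e-11). This was the 1 list of the comparison whose call held with an estimated correlation (adjusted p = 0.00735). They included Ptgs2, the inducible prostaglandin synthase (-1.49 ± 0.13 SE, adjusted p = 0.000154), the chemokine gene Ccl3 (-1.70 ± 0.20 SE, adjusted p = 0.000958) and Nfkbia, the inhibitor of NF-kB (-0.81 ± 0.08 SE, adjusted p = 0.000477). Interleukin 6 (Il6) fell as well, to 4.82 in E, under the median of all E probe sets (5.50, adjusted p = 0.0458), but its adjusted p lay between 0.0743 and 0.178 when WT replicates 1, 2 or 3, E replicates 2 or 3, or M replicates 1 or 2 were left out.

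Of 10 measured granulocyte genes, 5 rose, 2 fell and 3 did not pass (6 rose and 2 fell adjusted over the list alone), with a median log2 change of 1.56. The risen genes were S100a9, its partner S100a8 (2.24 ± 0.10 SE, adjusted p = 5.00e-07), and Lcn2, which binds bacterial siderophores (from 4.82, under the median of all WT probe sets of 5.64, to 7.14, adjusted p = 0.000199). They also included the granule protein genes Ngp (1.65 ± 0.14 SE, adjusted p = 0.000113) and Camp (1.48 ± 0.18 SE, adjusted p = 0.00151). The fallen members, picked out after their values were seen, were Mpo (-0.55, adjusted p = 0.00131, and 0.184 with arrays scaled on the spike-ins) and Ctsg (-0.40, adjusted p = 0.0441), proteins of early granules. The call of Ctsg ended without WT replicates 1, 2 or 3, E replicates 1, 2 or 3, or M replicate 1 (adjusted p from 0.0585 to 0.189). The granulocyte list was called higher (camera adjusted p = 2.16e-05, adjusted p = 0.227 with an estimated correlation), and not among the 4549 brightest genes (median 0.73 over 6 members, adjusted p = 0.0705). The median was 0.47 over 14 members without the filter and 0.89 over 12 with the mean of each gene's probe sets. Chil3, a secreted chitinase-like protein of myeloid cells, showed the largest rise of the comparison, 3.64 (log2) from 6.67 ± 0.11 to 10.31 ± 0.08 (SD, n = 3, adjusted p = 2.06e-09). Ear3 and Prg2, genes of eosinophil granules, rose 4.93-fold and 3.07-fold (adjusted p = 9.70e-05 for each).

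Beside this granulocyte rise, of 14 measured pan-hematopoietic genes, markers of blood cells at large, 0 rose, 1 fell and 13 did not pass (3 fell adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.000887, adjusted p = 0.401 with an estimated correlation). Ptprc, which encodes CD45, was at 9.76 ± 0.13 in WT and 9.59 ± 0.14 in E (SD, n = 3, adjusted p = 0.745). The member that fell was Lcp1 (-0.78 ± 0.17 SE, adjusted p = 0.0410), whose adjusted p was between 0.0533 and 0.182 without any 1 of the WT or E arrays or without M replicate 1. Without M replicate 3, Tyrobp (-0.65, adjusted p = 0.000132) and Laptm5 (-0.58, adjusted p = 0.000287) also passed as lower. Tyrobp passed without M replicate 2 as well (adjusted p = 0.0353). Other blood cell lists were not called. Erythroid genes had a median of -0.03 and a mean of -0.35, with 0 of 13 passing (camera adjusted p = 0.386, but 0.0429 without M replicate 3 and 8.26e-05 with spike-in scaling). Alas2 (-2.09) and Slc4a1 (-1.20), named after their values were seen, did not pass (adjusted p = 0.162 and 0.219), but had adjusted p of 8.31e-08 and 6.46e-07 without M replicate 3, in whose group they spread widely. Of 5 B lineage genes 0 passed (median 0.88, 2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.152). Megakaryocyte genes had 0 of 6 passing (median 0.34, 2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.101). Stem and progenitor genes had 0 of 7 passing (median -0.14, 1 fell adjusted over the list alone, camera adjusted p = 0.147).

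Of 17 fibroblast matrix genes, 1 rose, 5 fell and 11 did not pass (2 rose and 7 fell adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0158, adjusted p = 0.636 with an estimated correlation). That median lay between -0.10 and -0.34 without WT replicates 1 or 2 or E replicate 2. Fibronectin (Fn1) fell by 1.25 (SE 0.10, adjusted p = 9.70e-05), and the collagen VI genes Col6a3 and Col6a2 by -1.17 and -1.01 (adjusted p = 0.000183 and 0.00337). Postn and Col6a1 also fell and Col5a2 rose, each with a call that ended without any 1 of the WT or E arrays (adjusted p from 0.0828 to 0.133, from 0.0521 to 0.188 and from 0.101 to 0.148), and that of Col6a1 also without M replicate 2. Col6a1 and Col5a2 are named here after their values were seen. Of 11 genes of TGF-beta signalling, 2 fell and 9 did not pass (3 fell adjusted over the list alone, median -0.22, camera adjusted p = 0.000339, adjusted p = 0.346 with an estimated correlation). Those were Ccn2, a matricellular growth factor (-1.54 ± 0.07 SE, adjusted p = 7.40e-07), and Pmepa1, a feedback inhibitor (-0.85 ± 0.11 SE, adjusted p = 0.00161). Without M replicate 3, Tgfb2 (-0.97, adjusted p = 0.00581) and Tgfbi (-0.62, adjusted p = 0.000389) passed as lower too. In the mesenchymal niche list, 0 of 14 genes passed (1 rose and 2 fell adjusted over the list alone, median -0.30, camera adjusted p = 0.0806). Kitl (-0.57, adjusted p = 0.225), Lepr (-0.09, adjusted p = 0.899), Vcam1 (-0.21, adjusted p = 0.655), Angpt1 (-0.54, adjusted p = 0.333) and Csf1 (adjusted p = 0.727) were among those that did not pass. Pdgfra, the PDGF receptor of mesenchymal cells, was at 5.66 ± 0.44 in WT, near the median of all WT probe sets (5.64), and at 6.89 ± 0.13 in E (SD, n = 3, adjusted p = 0.0522, and 0.00174 without M replicate 3).

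Other lists were not called in this comparison. Among 9 osteoblast genes, Col1a1 (0.66 ± 0.14 SE, adjusted p = 0.0380) and Col1a2 (0.40 ± 0.07 SE, adjusted p = 0.0179) rose. Alpl (-1.02 ± 0.19 SE, adjusted p = 0.0179) fell and 6 did not pass (4 rose and 1 fell adjusted over the list alone, median 0.35, camera adjusted p = 0.0806). These calls ended without any 1 of the WT or E arrays for Col1a1 (adjusted p from 0.0710 to 0.151), without WT replicates 1 or 2 or E replicates 2 or 3 for Col1a2 (0.0567 to 0.101). That of Alpl ended without WT replicates 1 or 2 or E replicates 1 or 2 (adjusted p from 0.0612 to 0.0885). Of 13 hypoxia and glycolysis genes, Slc2a1 (-1.02, adjusted p = 0.00169), Hk2 and Ndrg1 fell and Aldoa and Ldha rose (2 rose and 4 fell adjusted over the list alone, median -0.09, camera adjusted p = 0.101). Among the 4549 brightest genes the hypoxia list held 5 members and was called higher (median 0.18, adjusted p = 0.0167). Those calls other than that of Slc2a1 were lost without single arrays. Hk2 lost its call without WT replicates 1 or 3 or E replicates 2 or 3 (adjusted p up to 0.111), Ldha without WT replicates 1 or 2 or any E array (up to 0.124). Those of Ndrg1 (up to 0.176) and Aldoa (up to 0.111) ended without any 1 of the WT or E arrays. These 5 genes were named after their values were seen. Of 5 Notch genes, 1 fell (2 fell adjusted over the list alone, median -0.07, camera adjusted p = 0.204). This was the ligand gene Jag1 (to 5.32 in E, under the median of all E probe sets of 5.50, adjusted p = 0.0437), whose call ended without WT replicates 1 or 3, any E array, or M replicates 1 or 2 (adjusted p from 0.0665 to 0.162).

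No gene passed in the lists of pericytes (0 of 6, 2 fell adjusted over the list alone, median -0.28, camera adjusted p = 0.127) or endothelium (0 of 7, 1 rose and 1 fell adjusted over the list alone, median 0.10, camera adjusted p = 0.541). Nor did any adipogenic gene (0 of 6, median 0.06, camera adjusted p = 0.704) or any gene of the cell cycle (0 of 20, median -0.10, camera adjusted p = 0.147). Genes of oxidative phosphorylation (0 of 19, median 0.08, camera adjusted p = 0.101) and of ribosomal proteins (0 of 14, median 0.04 and below 0 after quantile normalization, camera adjusted p = 0.285) did not pass either. The same held for the p53 list (0 of 9, 1 fell adjusted over the list alone, median 0.00, mean -0.04, camera adjusted p = 0.681). In the unfolded protein response 0 of 15 passed (1 fell adjusted over the list alone, median 0.00 and of the other sign after quantile normalization, camera adjusted p = 0.704). In the interferon response 0 of 7 passed (median -0.11 but mean 0.20 and test direction up, camera adjusted p = 0.793). Of the single genes fixed for all comparisons, Adipoq (0.20, adjusted p = 0.774), Acta2 (adjusted p = 0.745) and Mki67 (-0.24, adjusted p = 0.603) did not pass. Il7, Pecam1, Cdh5 and Hba-a1 lay under the brightness filter in mean signal, and without the filter their adjusted p values were 0.986, 0.904, 0.864 and 0.718.

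Across the 9097 genes, 192 (2.11%) differed between E and WT at an adjusted p under 0.05, 42 higher and 150 lower in E, and 1279 at an unadjusted p under 0.05. The 3 arrays of each group did not overlap in 2703 genes (29.7%), where chance gives 10%. Of the 24 lists tested, 7 were called, 1 higher and 6 lower. The count of genes depended on single arrays: it was 105, 113 and 98 without WT replicates 1, 2 and 3, 111, 106 and 105 without E replicates 1, 2 and 3, and 836 without M replicate 3, which shares in the estimate of spread. Without WT replicate 2, 12 lists were called, which added stem and progenitor genes (adjusted p = 0.0448), hypoxia genes (0.0448), megakaryocyte genes (0.0448), mesenchymal niche genes (0.0354) and osteoblast genes (0.0354). Further lists were called without WT replicate 3 (osteoblast 0.0389, oxidative phosphorylation 0.0232, ribosomal proteins 0.0232), E replicate 1 (pericyte 0.0489), E replicate 2 (osteoblast 0.0448), E replicate 3 (mesenchymal niche 0.0277) and M replicate 3 (cell cycle 0.0341, erythroid 0.0429).

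**Figure D1:**
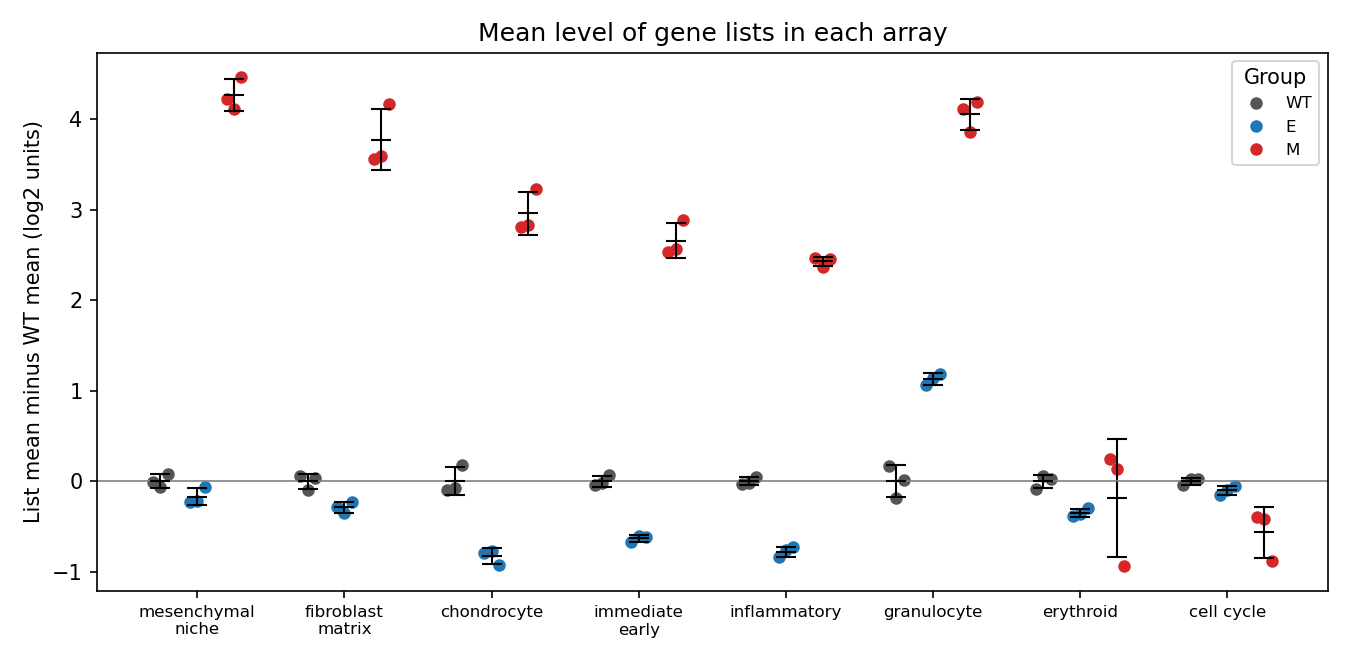
Mean log2 signal of the measured members of 8 gene lists in each array, given relative to the WT mean (y axis, log2) for WT, E and M (x axis). Points are arrays and bars are the mean ± SD of 3 arrays. The mesenchymal niche, fibroblast matrix, chondrocyte, immediate early, inflammatory and granulocyte lists are highest in M. All E arrays lie below the WT and M arrays for the chondrocyte, immediate early, inflammatory and fibroblast matrix lists. The niche and erythroid lists are lowest in E by their mean only.

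The comparison of M with WT asks what differs once leukemic cells make up 5 to 50% of the marrow. In M, genes of mesenchymal stromal cells were far above their WT signals. Cxcl12 rose 17.9-fold, from 8.63 ± 0.11 to 12.79 ± 0.03 (SD, n = 3, adjusted p = 4.91e-11), and Lepr, the leptin receptor that marks these cells, rose 36.5-fold, from 6.95 ± 0.39 to 12.14 ± 0.18 (SD, n = 3, adjusted p = 1.05e-08). Collagen III (Col3a1) rose 18.5-fold, from 10.41 ± 0.15 to 14.62 ± 0.15 (SD, n = 3, adjusted p = 8.75e-11).

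All gene list changes of this comparison are set against a median log2 change of -0.19 over the 9097 genes tested. Other scalings moved that median by -0.09 (quantile normalization), -0.10 (centring each array on its median) and -1.01 (arrays scaled on the poly-A spike-ins), and list medians below are therefore also given relative to all genes.

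All 14 measured mesenchymal niche genes rose, with a median log2 change of 4.28, or 4.46 relative to all genes (camera adjusted p = 1.54e-11, adjusted p = 0.0347 with an estimated correlation). Kitl, the stem cell factor, rose 18.2-fold (adjusted p = 2.52e-08), Pdgfrb 46.1-fold (adjusted p = 9.90e-10), and the adhesion molecule Vcam1 11.9-fold (adjusted p = 3.27e-08). Pdgfra rose to 11.64 ± 0.58 (SD, n = 3, adjusted p = 2.04e-08) from a WT signal (5.66) near the median of all WT probe sets, so its change has no exact size. Csf1, the macrophage growth factor, rose from 5.58 ± 0.44, under the median of all WT probe sets (5.64), to 9.93 ± 0.11 (SD, n = 3, adjusted p = 5.56e-08). Angpt1 rose by 1.20 ± 0.23 SE (adjusted p = 0.000868), and by 0.19 without passing (adjusted p = 0.519) when the arrays were scaled on the spike-ins. All 6 tested pericyte genes rose (of 12 on the array, median 3.54, relative 3.73, camera adjusted p = 3.62e-05, adjusted p = 0.0347 with an estimated correlation), among them Acta2, the actin of smooth muscle (4.21 ± 0.42 SE, adjusted p = 7.14e-06). Only 1 of these 6 had a WT mean above the brightness filter, so the other 5 were tested because of their signal in M. Of the 52 tested genes of the niche, matrix, osteoblast, pericyte and adipogenic lists, 34 had a WT mean above the filter, and 33 of these rose. All 6 adipogenic genes rose (median 2.53, relative 2.72, camera adjusted p = 5.44e-05, adjusted p = 0.0347 with an estimated correlation), among them Adipoq, the hormone of fat cells (3.12 ± 0.25 SE, adjusted p = 1.12e-06).

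Of 17 fibroblast matrix genes, 16 rose and 1 did not pass, with a median of 4.15, relative 4.34 (camera adjusted p = 3.60e-12, adjusted p = 0.109 with an estimated correlation). The collagen-binding proteoglycans Lum and Dcn rose 18.7-fold and 17.7-fold (adjusted p = 2.14e-10 and 9.90e-10), and Fn1 7.47-fold (adjusted p = 3.33e-09). All 13 chondrocyte genes rose (median 2.93, relative 3.12, camera adjusted p = 2.95e-10, adjusted p = 0.0958 with an estimated correlation). Matn3 (2.98 ± 0.10 SE), the cartilage proteoglycan Acan (2.93 ± 0.11 SE) and Cnmd (2.81 ± 0.11 SE) were among them. All 9 osteoblast genes rose (median 2.82, relative 3.01, camera adjusted p = 2.90e-06, adjusted p = 0.0501 with an estimated correlation), including the bone matrix protein Ibsp 12.5-fold, the phosphatase Alpl 7.06-fold and Col1a1 5.37-fold. Col8a1, a short-chain collagen, rose 67.4-fold, from 6.67 ± 0.26 to 12.75 ± 0.18 (SD, n = 3, adjusted p = 2.11e-10). Ccn3 and Aspn, both secreted matrix proteins, rose too, Ccn3 69.5-fold. The WT arrays of Aspn read 5.67 to 6.21, near the median of all WT probe sets (5.64), so its change has no exact size.

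Signalling lists rose beside them. All 18 immediate early genes rose (median 2.93, relative 3.12, camera adjusted p = 3.60e-12, adjusted p = 0.0616 with an estimated correlation), with Egr1 up 16.5-fold (adjusted p = 1.62e-11). The cytokine inhibitor Socs3 rose 33.4-fold (adjusted p = 3.76e-09) and Klf4 12.9-fold (adjusted p = 5.43e-09). Of 12 inflammatory mediators, 11 rose and 1 did not pass (median 2.40, relative 2.59, camera adjusted p = 1.37e-07, adjusted p = 0.0272 with an estimated correlation). The neutrophil chemokine Cxcl1 rose 20.8-fold (adjusted p = 2.54e-09) and Ptgs2 6.14-fold (adjusted p = 2.95e-08). Il6 rose as well (adjusted p = 6.13e-08). Its WT arrays read 5.75 to 6.30, near the median of all WT probe sets (5.64), so its change has no exact size. Of 11 TGF-beta genes, 10 rose and 1 did not pass (median 2.61, relative 2.80, camera adjusted p = 3.88e-07, adjusted p = 0.0825 with an estimated correlation). The receptor gene Tgfbr2 (3.46 ± 0.15 SE), Skil (2.96 ± 0.13 SE) and Pmepa1 (2.83 ± 0.11 SE) were among them. Of 13 hypoxia and glycolysis genes, 11 rose, 1 fell and 1 did not pass (median 2.11, relative 2.30, camera adjusted p = 3.38e-06, adjusted p = 0.126 with an estimated correlation), and a median of 0.36 over 5 members among the 4549 brightest genes. The fallen member was Pdk1, a kinase that holds back pyruvate oxidation. Of 15 genes of the unfolded protein response, 12 rose, 1 (Asns) fell and 2 did not pass, with a median of 0.62, relative 0.81, that turned to -0.39 with spike-in scaling (camera adjusted p = 7.77e-05, adjusted p = 0.0825 with an estimated correlation). Pdk1 and Asns were picked out after their values were seen.

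All 10 granulocyte genes rose (median 4.88, relative 5.06, camera adjusted p = 3.99e-09, adjusted p = 0.0501 with an estimated correlation), with S100a9 up 87.7-fold, Camp 37.2-fold and Ngp 25.2-fold. S100a8 reached 15.13 ± 0.08 (SD, n = 3), where the brightest probe set of an M array read 15.13 to 15.34, so its rise is given as at least 50.1-fold. Chil3 rose 269-fold to 14.74 ± 0.10 (SD, n = 3, adjusted p = 3.65e-13). Of 14 pan-hematopoietic genes, 11 rose, 1 (Ikzf1) fell and 2 did not pass (median 1.09, relative 1.28, and 0.08 with spike-in scaling, camera adjusted p = 0.000544, adjusted p = 0.294 with an estimated correlation). Ptprc rose by 0.87 ± 0.19 SE (adjusted p = 0.00192), and with spike-in scaling its change was -0.14 (adjusted p = 0.544). Of 6 megakaryocyte genes, Clec1b, Itga2b, Pf4, Ppbp and Tubb1 rose and Gp9 fell (median 0.94, relative 1.13, and -0.07 with spike-in scaling, camera adjusted p = 0.0410, adjusted p = 0.126 with an estimated correlation). With that scaling the changes of Itga2b, Pf4 and Tubb1 were below 0. The list's call was lost without WT replicate 1 (adjusted p = 0.0541), without M replicate 3 (0.05004), without the brightness filter, with quantile normalization and with spike-in scaling (0.292). Of 5 B lineage genes, Blnk, Cd79b, Igll1 and Vpreb1 rose and Dntt fell (median 1.92, relative 2.11, camera adjusted p = 0.0657, and 0.0394 without M replicate 2). Of 13 erythroid genes, 3 fell and 10 did not pass (median -0.20, relative -0.01, camera adjusted p = 0.445), and the median was 0.04 without M replicate 3. The fallen ones were the erythroid regulators Gata1 (-0.86, adjusted p = 1.20e-05), Epor (-0.78, adjusted p = 1.49e-05) and Klf1 (-0.56, adjusted p = 0.0148, and 0.0600 without WT replicate 3). Ikzf1 and the named megakaryocyte, B lineage and erythroid genes were picked out after their values were seen.

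Of 20 cell cycle genes, 17 fell, 0 rose and 3 did not pass (median -0.60, relative -0.41, camera adjusted p = 0.00377, adjusted p = 0.483 with an estimated correlation). Relative to all genes, the cell cycle median was -0.24 without M replicate 3 and -0.24 after quantile normalization. The mitotic kinases Plk1 (-1.01) and Cdk1 (-0.84) fell. Mki67, a marker of dividing cells, was at 13.27 ± 0.04 in WT and 13.30 ± 0.45 in M (SD, n = 3, adjusted p = 0.907), and differed by 0.27 without M replicate 3 (adjusted p = 0.0242) and by -0.99 with spike-in scaling. Of 19 genes of oxidative phosphorylation, 17 fell and 2 did not pass (median -0.40, relative -0.21, camera adjusted p = 0.00152, adjusted p = 0.338 with an estimated correlation, and 0.0723 with spike-in scaling). Relative to all genes, the oxidative phosphorylation median was 0.005 after quantile normalization and -0.06 among the 4549 brightest genes. Ribosomal protein genes were not called as a list (4 of 14 fell, namely Rpl14, Rps19, Rps6 and Rps9, median -0.15, relative 0.04, camera adjusted p = 0.291). Single falls were small beside the rises: the 10 largest ranged from -1.54 for Pdia2 to -1.30 for Chtf18, with Hpn, a membrane serine protease, at -1.51 ± 0.09 SE (adjusted p = 1.02e-07). Plk1, Cdk1 and the named ribosomal genes were picked out after their values were seen.

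In the endothelial list, Cldn5, Erg, Esam and Plvap rose, Egfl7 and Eng fell and 1 did not pass (of 7, median 0.94, relative 1.12, and -0.07 with spike-in scaling, camera adjusted p = 0.0919), and the change of Plvap was also below 0 with that scaling. In the p53 list, Cdkn1a, Bbc3, Sesn2 and Trp53inp1 rose, Ccng1 and Zmat3 fell and 3 did not pass (of 9, 5 rose and 2 fell adjusted over the list alone, median 0.40, relative 0.59, and -0.61 with spike-in scaling, camera adjusted p = 0.0657, and 0.0479 without WT replicate 3). With spike-in scaling the changes of Bbc3, Sesn2 and Trp53inp1, and of Hoxa9 in the next list, were below 0. In the stem and progenitor list, Cd34, Hoxa9 and Procr rose, Cd48, Kit and Myb fell and 1 did not pass (of 7, median 0.08, relative 0.27, below 0 under quantile normalization, centring and spike-in scaling, camera adjusted p = 0.284). The call of Kit was lost without WT replicates 1 or 3, E replicates 2 or 3, or M replicates 2 or 3 (adjusted p up to 0.157). In the Notch list, Jag1 (14.9-fold, adjusted p = 3.42e-08) and Notch1 rose and 3 did not pass (of 5, median 0.06, relative 0.24, below 0 with centring and spike-in scaling, camera adjusted p = 0.0689). In the interferon list, Gbp2 and Rsad2 rose, Ifit2 and Usp18 fell and 3 did not pass (of 7, median -0.19, relative -0.004, mean 0.63 and test direction up, camera adjusted p = 0.723). The members named here were picked out after their values were seen, apart from Jag1. Il7, Cdh5 and Pecam1, under the filter in mean signal, were higher in M without the filter (adjusted p = 0.000296, 0.000992 and 0.0439), and Hba-a1 did not pass (adjusted p = 0.0623). Their WT means (4.96, 5.46, 4.07 and 2.28) lay under the median of all WT probe sets (5.64), so no size is given.

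In total 6259 genes (68.8%) differed between M and WT, 2306 higher and 3953 lower in M. That balance depends on the processing. Without the brightness filter 4032 were higher and 3848 lower, and with a 2-fold minimum 1291 and 165. Scaled on the spike-ins, 966 were higher and 7222 lower, and among the 4549 brightest genes 698 were higher and 2768 lower. Changes of 8-fold or more comprised 428 rises and 0 falls. The arrays of M and WT did not overlap in 6553 genes (72.0%, where chance gives 10%). Of 24 lists, 16 were called, 14 higher and 2 lower, and 4 calls held with an estimated correlation: the mesenchymal niche, pericyte, adipogenic and inflammatory lists. Of their tested members, 10 of 14, 1 of 6, 5 of 6 and 8 of 12 had a WT mean above the brightness filter. The others entered the test through their signal in other groups.

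**Figure D2:**
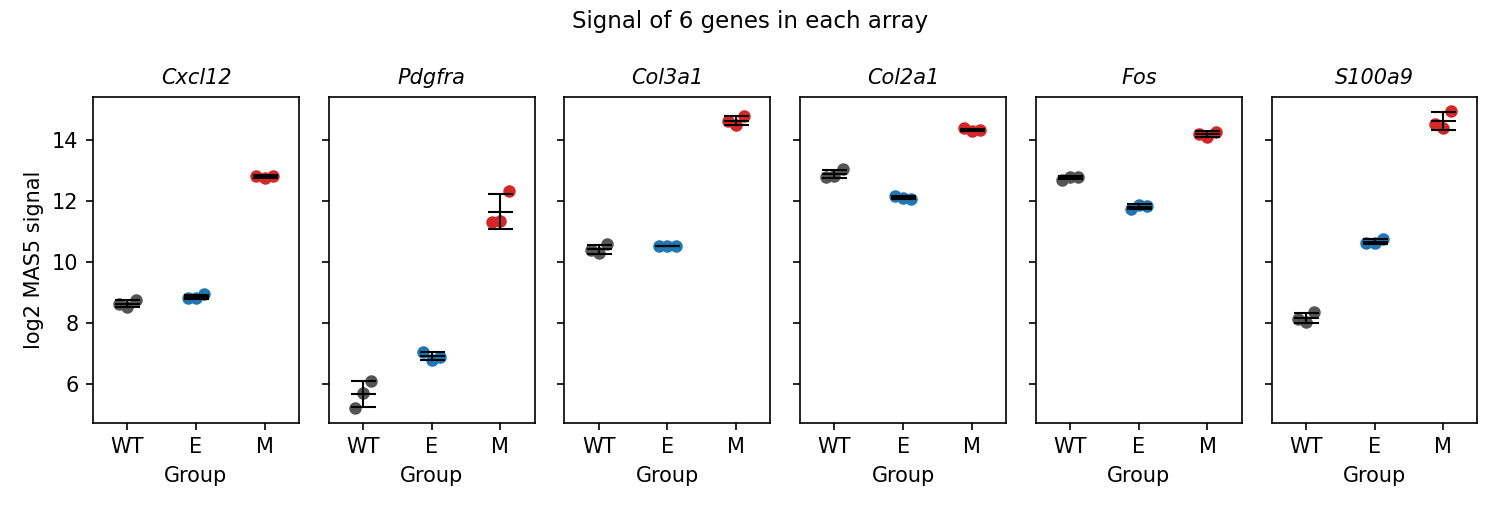
Log2 MAS5 signal (y axis) of Cxcl12, Pdgfra, Col3a1, Col2a1, Fos and S100a9 in each array of WT, E and M (x axis). Points are arrays and bars are the mean ± SD of 3 arrays. All M arrays lie above the WT and E arrays, and the E arrays lie below the WT arrays for Col2a1 and Fos and above them for S100a9.

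The comparison of M with E asks what changes over the step in which leukemic cells expand. Most mesenchymal genes rose over this step. Cxcl12 rose by 3.94 ± 0.08 SE (log2, adjusted p = 8.89e-11), Lepr 38.9-fold (adjusted p = 6.41e-09) and Pdgfra 26.8-fold (adjusted p = 8.84e-08). Kitl rose too (adjusted p = 6.97e-09). Its E arrays read 5.65 to 5.96, near the median of all E probe sets (5.50), so its change has no exact size. Genes that had been lower in E rose as well, among them Fos 5.18-fold from 11.81 ± 0.07 to 14.18 ± 0.09 (SD, n = 3, adjusted p = 4.25e-10). Fn1 rose 17.8-fold from 9.96 ± 0.06 to 14.11 ± 0.18 (SD, n = 3, adjusted p = 2.09e-10). The matrix protein gene Postn rose by 6.90 ± 0.26 SE (log2). Aspn, another matrix protein, and the growth factor Ptn rose to 12.13 ± 0.70 and 11.60 ± 1.06 (SD, n = 3) from signals under the median of all E probe sets (4.76 and 4.81 against 5.50), so their change has no exact size.

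The median over all tested genes was -0.19 and moved by -0.10, -0.12 and -1.02 with quantile normalization, centring and spike-in scaling. All 14 mesenchymal niche genes rose (median 4.75, relative 4.94, camera adjusted p = 3.53e-11, adjusted p = 0.0373 with an estimated correlation). So did all 6 pericyte genes (3.63, relative 3.82, camera adjusted p = 4.66e-05, adjusted p = 0.0373 with an estimated correlation). The same was true of all 6 adipogenic genes (2.60, relative 2.79, camera adjusted p = 0.000115, adjusted p = 0.0373 with an estimated correlation). Vcam1 (3.78), Angpt1 (1.73, adjusted p = 5.37e-05), Acta2 (from 5.80 ± 0.69 to 10.38 ± 0.90, SD, n = 3) and Adipoq (2.92) rose among the fixed genes. Csf1 rose as well, from 5.56 to 5.98 in the E arrays, near the median of all E probe sets (5.50), to between 9.81 and 10.02 in the M arrays. All 18 immediate early genes rose (median 3.59, relative 3.78, camera adjusted p = 7.70e-13, adjusted p = 0.0603 with an estimated correlation), with Egr1 up 25.9-fold (adjusted p = 1.29e-11) and Jun 4.61-fold. All 12 inflammatory mediators rose (median 3.21, relative 3.397, camera adjusted p = 2.12e-08, adjusted p = 0.0197 with an estimated correlation), with Cxcl1 up 38.0-fold and Ptgs2 17.2-fold. Il6 rose to 10.71 ± 0.28 (SD, n = 3) from a signal in E (4.82) that lay under the median of all E probe sets (5.50). All 13 chondrocyte genes rose (median 3.71, relative 3.90, camera adjusted p = 8.54e-11, adjusted p = 0.0870 with an estimated correlation), with Comp up 10.2-fold and Matn3 13.1-fold. Of 17 fibroblast matrix genes, 16 rose and 1 did not pass (median 4.29, relative 4.48, camera adjusted p = 4.61e-12, adjusted p = 0.113 with an estimated correlation). Of 11 TGF-beta genes, 10 rose and 1 did not pass (median 3.36, relative 3.54, camera adjusted p = 4.33e-07, adjusted p = 0.0870 with an estimated correlation), with Ccn2 up 10.2-fold. Of 9 osteoblast genes, 8 rose (9 adjusted over the list alone) and 1 did not pass (median 2.16, relative 2.35, camera adjusted p = 2.65e-05, adjusted p = 0.0603 with an estimated correlation), with Ibsp (3.59), Omd (from 5.92 ± 0.48 to 10.66 ± 0.66, SD, n = 3) and Col1a1 (1.77) up. Jag1 rose to 10.13 ± 0.29 (SD, n = 3, adjusted p = 5.48e-09), also from under that median (5.32).

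All 10 granulocyte genes rose over the step (median 3.01, relative 3.20, camera adjusted p = 6.07e-08, adjusted p = 0.0603 with an estimated correlation), now including Ctsg (2.85 ± 0.09 SE) and Mpo (1.68 ± 0.07 SE). Of 14 pan-hematopoietic genes, 11 rose, 1 (Ikzf1) fell and 2 did not pass (median 1.33, relative 1.51, camera adjusted p = 0.000115, adjusted p = 0.238 with an estimated correlation). Ptprc rose by 1.05 ± 0.19 SE (adjusted p = 0.000546), and by 0.03 with spike-in scaling (adjusted p = 0.898). Of 13 hypoxia genes, 10 rose, Ldha and Pdk1 fell and 1 did not pass (median 2.30, relative 2.48, camera adjusted p = 4.02e-05, adjusted p = 0.189 with an estimated correlation, and 0.188 among the 4549 brightest genes, where the median was 0.02). Of 15 genes of the unfolded protein response, 12 rose, Asns fell and 2 did not pass (median 0.59, relative 0.78 and -0.42 with spike-in scaling, camera adjusted p = 0.000146, adjusted p = 0.0870 with an estimated correlation). Of 19 genes of oxidative phosphorylation, 18 fell and 1 did not pass (median -0.44, relative -0.25, camera adjusted p = 0.00112, adjusted p = 0.342 with an estimated correlation, and 0.0624 with spike-in scaling). Their relative median was -0.01 after quantile normalization and -0.11 among the 4549 brightest genes. Of 20 cell cycle genes, 17 fell and 3 did not pass (18 fell adjusted over the list alone, median -0.51, relative -0.32, camera adjusted p = 0.0178, adjusted p = 0.571 with an estimated correlation, and up to 0.160 in the 4549 brightest genes and after quantile normalization, where the call was lost). Their relative median was -0.18 without M replicate 3 and -0.09 after quantile normalization. Mki67 differed by 0.26 (adjusted p = 0.209), by 0.50 without M replicate 3 (adjusted p = 0.000380) and by -0.76 with spike-in scaling. Ikzf1, Ldha, Pdk1 and Asns were picked out after their values were seen.

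Of the lists not called between M and E, B lineage genes had 3 of 5 higher (Blnk, Cd79b and Igll1, median 1.21, relative 1.40, camera adjusted p = 0.105). Megakaryocyte genes had 5 of 6 higher (Clec1b, Itga2b, Pf4, Ppbp and Tubb1) and Gp9 lower (median 0.65, relative 0.84, and -0.37 with spike-in scaling, camera adjusted p = 0.106). With that scaling Clec1b, Itga2b, Pf4 and Tubb1 were below 0, and Tubb1 did not pass without E replicate 1 or M replicate 2 (adjusted p up to 0.0672). Endothelial genes had 4 higher (Cldn5, Erg, Esam and Plvap), Egfl7 and Eng lower and 1 not passing (median 0.84, relative 1.03, and -0.18 with spike-in scaling, as for Plvap, camera adjusted p = 0.155). In the p53 list, Cdkn1a, Bbc3 and Trp53inp1 rose, Ccng1 and Zmat3 fell and 4 did not pass (median 0.25, relative 0.43, below 0 after quantile normalization and spike-in scaling, camera adjusted p = 0.117). Jag1 and Notch1 rose among 5 Notch genes (median 0.01, relative 0.20, below 0 with centring and spike-in scaling, camera adjusted p = 0.122). Of 14 ribosomal protein genes, 8 fell (median -0.20, relative -0.01, camera adjusted p = 0.192). In the stem and progenitor list, Cd34, Hoxa9 and Procr rose, Hoxa9 with a change below 0 under spike-in scaling, and Cd48, Kit and Myb fell (median 0.25, relative 0.44, below 0 after quantile normalization and spike-in scaling, camera adjusted p = 0.199). Cd48 and Kit did not pass without E replicate 1 (adjusted p = 0.0740 and 0.0600). In the interferon list, Gbp2 rose, Bst2 and Usp18 fell and 4 did not pass (median -0.14, relative 0.05, camera adjusted p = 0.884), and Usp18 did not pass without E replicates 1 or 2 (adjusted p up to 0.0577). Among 13 erythroid genes, Gata1, Epor and Klf1 fell, Alas2, the enzyme that starts heme synthesis, and Slc4a1 rose and 8 did not pass (median -0.14, relative 0.05, but mean 0.16, camera adjusted p = 0.812). The call of Slc4a1 ended without any E array or without M replicates 1 or 2 (adjusted p from 0.0502 to 0.104), that of Klf1 without E replicates 2 or 3 (0.0502 to 0.0566). Members named here were picked out after their values were seen, apart from Jag1. Without the brightness filter, Il7, Pecam1 and Cdh5 were higher in M than in E (adjusted p = 0.000233, 0.0191 and 0.000374), and Hba-a1 did not pass (adjusted p = 0.337). Their E means also lay under the median of all E probe sets (5.50).

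In all, 6368 genes (70.0%) differed between M and E, 2376 higher and 3992 lower in M. The balance turned without the brightness filter, with 4382 higher and 3892 lower, and with a 2-fold minimum, with 1345 and 265. With spike-in scaling these were 1031 higher and 7179 lower, and among the 4549 brightest genes 742 higher and 2743 lower. Falls reached at most -1.73 (Hpn, adjusted p = 2.62e-08), while 532 genes rose 8-fold or more. Arrays of M and E did not overlap in 6650 genes (73.1%, where chance gives 10%). Of 24 lists, 15 were called, 13 higher and 2 lower, and the calls that held with an estimated correlation were again those of the mesenchymal niche, pericyte, adipogenic and inflammatory lists. The limit given for M and WT holds here too, most of all for the pericyte list, where 1 of 6 members had a WT mean above the brightness filter.

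**Figure D3:**
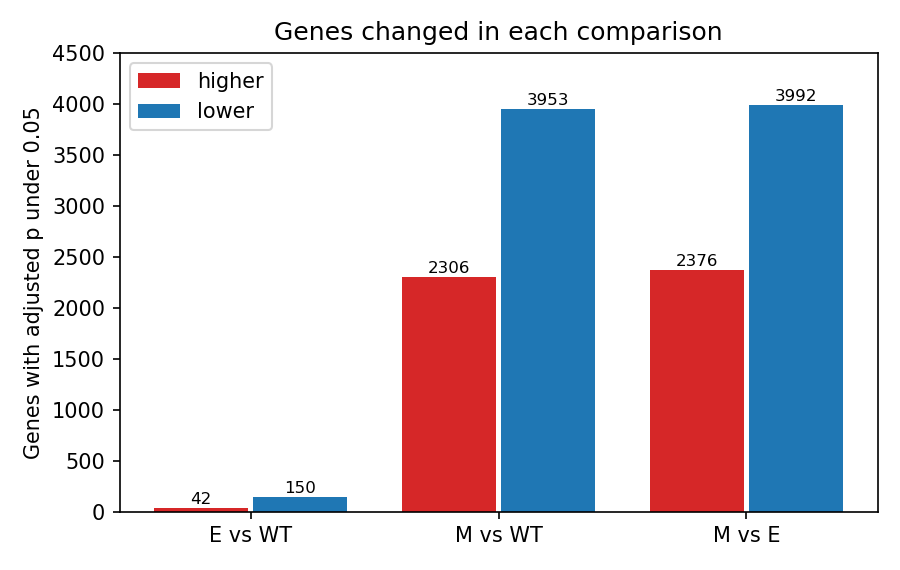
Number of genes (y axis, from 0) with an adjusted p under 0.05 that were higher or lower in each of the 3 comparisons (x axis), out of 9097 tested. E vs WT gave 42 higher and 150 lower, M vs WT 2306 and 3953, and M vs E 2376 and 3992.

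Taking the 3 groups in order asks whether expression moved gradually. In both steps 17 genes rose and 2 fell, out of the 192 that passed in the first. The genes that rose in both steps included Chil3, S100a9, S100a8, Lcn2, Ngp and Camp, and also Acta1, an actin of skeletal muscle. Those that fell in both steps were Redrum, a noncoding RNA, and Afg3l1, which was named after its values were seen. Both lost their E call without any 1 of the WT or E arrays (adjusted p up to 0.187 and 0.163), Redrum also without M replicate 2. By contrast, 136 genes fell from WT to E and rose from E to M. Among these were Ccn2, Fn1, Ptgs2, Bmp2, a bone growth factor, and Timp3, a metalloproteinase inhibitor. A further 20 genes rose and then fell. In 100 simulated data sets with E equal to WT and genes drawn independently, at most 0 genes fell and then rose and at most 1 rose and then fell. Noise shared between genes was not part of these data sets. An F test over the 3 groups called 6386 genes. The steps differed in size in 4661 genes (51.2%), 1875 with the second step more positive and 2786 with it more negative, and in 4290 of the 6259 genes that differed between M and WT. Without the brightness filter these were 5572 genes, 2986 more positive and 2586 more negative, and with spike-in scaling 7055, of which 917 and 6138.

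Of the 6259 genes that differed between M and WT, 2554 (40.8%) had an E mean between the WT and M means. Simulated data in which E equalled WT, with genes drawn independently, gave 53.3% (51.0 to 54.8 over 100 simulations). Of the 150 genes lower in E, 123 were higher in M than in WT, where 38.0 would be expected if the calls were independent, and 14 were lower (65.2 expected). Of the 42 genes higher in E, 22 were higher in M (10.6 expected) and 13 lower (18.3 expected). Both calls use the WT arrays, which draws them to the same direction. The expected counts are therefore not those without true change, which were not computed for this overlap. Across genes, which are not independent replicates, the changes from WT to E and from WT to M had a correlation of -0.185, and 0.159 without the brightness filter. Both changes share the WT arrays, which alone gave correlations of 0.450 to 0.551 in simulated data without true change and with genes drawn independently. With the WT arrays divided between the changes, a check chosen after the correlation was seen, it lay between -0.216 and -0.173 over 6 divisions, and without the brightness filter between -0.0669 and -0.0489.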

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

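The tests of scaling and of cell composition in this part were chosen after the results had been seen, and the splits of the arrays before. Gene lists called lower in E than in WT and higher in M than in WT were singled out because the groups differ in opposite directions from the same control with the fixed correlation. The median log2 difference of M minus E, tested by camera, was 3.59 for immediate early genes, 4.29 for fibroblast matrix genes, 3.71 for chondrocyte genes, 3.21 for inflammatory genes, 3.36 for TGF-beta genes and 1.33 for pan-hematopoietic genes. With an estimated correlation the inflammatory list kept its calls, and the other 5 lost them against WT both in E (adjusted p from 0.114 to 0.636) and in M (0.0616 to 0.294), and their calls between M and E as well (0.0603 to 0.238). The poly-A spike-ins, control probe sets outside the gene measurement, were singled out because they read higher in M than in WT, by 1.01 in log2 (exact permutation p = 0.1). Single far samples were not tested in groups of 3 arrays.

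The mesenchymal lists (niche, fibroblast matrix, osteoblast, pericyte and adipogenic) were higher in M than in WT, though with an estimated correlation the fibroblast matrix and osteoblast lists lost that call (adjusted p = 0.109 and 0.0501). A uniform shift the size of the spike-in difference was too small to be the whole cause. With the arrays scaled on the spike-ins, the lowest M array still lay 1.11 above the highest WT array in the list with the smallest gap. This was over members with a WT mean above the brightness filter, which for the pericyte list was 1 gene. Effects of RNA amount or background that depend on signal height were not tested, and exact zeros and array medians differed in M. A loss of the most abundant cells could raise all other cell types alike. This was tested on the 5 megakaryocyte and 6 endothelial genes with such a WT mean. The lower quartile of such niche genes (3.61) lay 2.56 above the higher of their upper quartiles (megakaryocyte 0.96, endothelial 1.06). These values do not settle the question for endothelium at large, because only 7 of the 20 endothelial genes passed the brightness filter. Over all 20, the mean log2 signal was 6.10 in WT and 7.43 in M, and over all 17 niche genes 6.81 and 10.82. Whether the most abundant cells also express the tested genes was not tested. Such a loss was not excluded, also because granulocyte genes rose about as far as the niche genes (median 3.75 over such members). The endothelial genes Cdh5 and Pecam1, too dim for the test, were also higher in M without the filter. Whether the sorted cells held a larger share of mesenchymal cells or each cell changed its expression was not tested. An effect of the leukemic phase on either was not tested, because no group separates phase from sorting or array handling.

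Of 10 granulocyte genes, 5 rose and 2 fell in E, with the list's call lost at an estimated correlation (adjusted p = 0.227). A uniform shift of the arrays, as read by the spike-ins, was excluded as the cause of their median change of 1.56. That median lay 1.44 above the largest shift of any poly-A spike-in probe set between E and WT (0.13). It covers 10 members, 8 of them with a WT mean above the brightness filter. Without the filter and among the brightest genes the median was smaller, as given above. Effects that depend on signal height were not tested. Granulocytes among the sorted cells and expression by the stromal cells cannot be told apart. Pan-hematopoietic genes had a median change of -0.31 with 13 of 14 not passing, though Tyrobp and Laptm5 were also called lower without M replicate 3. The pan-hematopoietic genes were measured in WT already, so a small added share of granulocytes could go unseen in them. The CD45.1 gate is meant to remove such cells, yet Ptprc, which encodes CD45, was measured at 9.76 in WT and 9.59 in E. A signal of that height can hide a small added share. Whether leukemic cells passed the gate and added to the granulocyte genes was not tested.

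Chondrocyte and other lists were called lower in E and higher in M, calls that for chondrocyte genes were lost with an estimated correlation (adjusted p = 0.114 and 0.0958). A uniform shift of the arrays, as read by the spike-ins, was excluded as the cause of the chondrocyte fall. Its median of -0.77 lay 0.62 under the lowest shift of any spike-in probe set (-0.15). Effects that depend on signal height were not tested. Values of the osteoblast and niche genes argue against fewer stromal cells of every kind alike as the whole cause of the chondrocyte fall. Over members with a WT mean above the filter, their lower quartiles (osteoblast 0.05, niche -0.53) lay above the upper quartile of the chondrocyte genes (-0.73), the nearer by 0.21. The lower quartile of the fibroblast matrix genes (-1.01) lay under that value, so the fibroblast matrix list was not set apart. A smaller loss shared by several kinds stays open, because the medians of the niche (-0.30), pericyte (-0.28) and fibroblast matrix lists (-0.18) were below 0. Immediate early genes respond to tissue dissociation, and no value here tests whether handling differed between the groups.

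Other assignments of the arrays to groups were tried. For E and WT there are 10 splits of the 6 arrays, too few for a share under 0.05: the real split gave 192 genes and was 1 of 10, with 0 genes as the highest other count, and 7 lists, which 2 of 10 splits reached, with 8 as the highest other. For M and WT the real split gave 6259 genes (1 of 10, highest other 0) and 16 lists (6 of 10, highest other 19). For M and E it gave 6368 genes (1 of 10, highest other 0) and 15 lists (7 of 10, highest other 18). In the comparisons with M, most splits thus called at least as many lists as the real groups. In every other split of 6 arrays, however, the arrays of a group lie unevenly on its sides. Part of the group difference therefore stays in these splits. Their list counts do not show how many lists would be called without a difference. Over 100 splits of the 9 arrays, the F test reached its real count of 6386 in 1 (highest other 5967), and the test of even steps reached 4661 in 3 (highest other 6695). The high counts came from splits that kept the M arrays together: 5 such splits of the F test gave up to 5967 genes and 94 that parted them up to 2, and for even steps 4 gave up to 6695 and 95 up to 2, so these counts point to the structure of the samples, M against the rest.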

How the results depend on the processing

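Under the alternatives, 152 counts stayed within 1.5 times the main count, 8 rose and 21 fell beyond it, and single named genes kept direction and side of the threshold in 4057 of their results, gained a call in 28, lost it in 106 and reversed in 3. The number of genes differing between E and WT (192) was 85 among the 4549 brightest genes, where fewer genes were tested, 118 with quantile normalization, 99 with the mean of a gene's probe sets, 66 with a 2-fold minimum, 330 at an adjusted p under 0.1, 848 with array weights and 756 with only those 2 groups fitted, and lay between 98 and 836 with single arrays left out. The other gene counts fell with the 4549 brightest genes (M and WT 3466, M and E 3485, F test 3531, even steps 2633) and with a 2-fold minimum (M and WT 1456, M and E 1610), by construction. With arrays left out they ranged from 5721 to 6334 for M and WT, 5782 to 6462 for M and E, 5995 to 6607 for the F test and 3686 to 5257 for even steps. Scaling on the poly-A spike-ins, an alternative chosen after the data were seen, gave 7055 genes with uneven steps and 12 lists for E and WT. With an estimated correlation, 1, 4 and 4 lists were called for E and WT, M and WT, and M and E. With the brightest genes, 8 of 10 and 6 of 10 testable lists were called for M and WT and for M and E, and without the filter 23 of 31 for M and E. With arrays left out, 7 to 12, 15 to 17 and 15 to 15 lists were called. The correlation of the changes from WT to E and from WT to M across genes (-0.185) became 0.159 without the filter, and -0.0533 there with the WT arrays divided between the changes, also chosen after the data were seen. Spike-in scaling reversed Ptprc in M and WT (-0.14) and Mki67 in M and WT (-0.99) and M and E (-0.76), as a shift of all genes by about the spike-in difference does by construction. With the replicate number as a replicate block, 153, 6100 and 6248 genes and 9, 16 and 15 lists were called. The E and WT count rose to 836 without M replicate 3 and to 756 with only those 2 groups fitted. M arrays enter that comparison only through the estimate of spread, so these rises came from a smaller estimate. Apart from this, fewer genes tested, a stricter rule or the spike-in shift, the cause was not tested.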

Other observations

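Gene groups too dim for the main test and single genes outside the lists add to the picture, and were looked at after the main results. Without the brightness filter, 12 of 14 Wnt pathway genes were higher in M than in WT and 0 passed between E and WT. Their WT mean (5.09) lay under the median of all WT probe sets (5.64). The list holds secreted Wnt inhibitors, such as the Sfrp and Dkk genes, beside ligands and targets, so the count is no measure of pathway activity. Skeletal muscle genes had 7 of 12 higher in M than in WT and 2 of 12 higher in E than in WT. Acta1, the actin of skeletal muscle, rose in E (adjusted p = 0.00121). Its WT arrays read 5.49 to 6.16, near the median of all WT probe sets (5.64), so its change has no exact size. Plasma cell genes had 6 of 8 higher in M than in WT and 1 lower in E, and Igha, the heavy chain of immunoglobulin A, went from 9.56 in WT to 7.51 in E (adjusted p = 0.00584) and 9.77 in M. Monocyte genes had 5 of 12 higher and 1 lower in M than in WT and osteoclast genes 3 of 10 higher and 1 lower. T and NK cell genes had 2 of 13 higher and Schwann cell genes 2 of 7 higher and 1 lower. The eosinophil granule genes Ear3 and Prg2 stood at 10.64 and 10.82 in E and at 10.75 and 10.98 in M, from 8.34 and 9.20 in WT.

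The third M array differed from the other M arrays in several lists. Its erythroid genes were lower by a median of -0.66 (12 of 13 lower) and its cell cycle genes by -0.48 (19 of 20 lower), while its fibroblast matrix genes were higher by 0.51 (16 of 17), its pan-hematopoietic genes by 0.59 (13 of 14) and its B lineage genes by 0.88 (4 of 5). Alas2 read 11.74 and 11.58 in M replicates 1 and 2 and 8.50 in M replicate 3, with 9.69 to 9.90 in WT and 7.49 to 7.90 in E. Rsad2, an antiviral gene induced by interferon, read 12.26, 12.23 and 9.30 in M replicates 1, 2 and 3.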
